A study of Mus musculus with 24 samples.

How the data were processed

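RNA of C2C12 cells, a line of mouse myoblasts, was measured on 24 Affymetrix mouse arrays, 3 in each of 8 groups. The groups crossed siRNA against IFT88 (written IFT88KD) or a negative control siRNA (control) with 4 culture states. Proliferating cells grew attached in medium with 20% fetal bovine serum, quiescent cells were held in suspension, replated cells were taken 2 h after they were put back on a surface, and differentiating cells spent 48 h in medium with 2% horse serum, per the labels' protocols. Total RNA was extracted with TRIzol and 8 ug of it went into biotin-labelled cRNA, per the labels' protocols.

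The deposited table held log2 expression values of 22690 probe sets, none of them missing, with 0 columns of other samples. GCOS, Affymetrix Expression Console and affy were used to make the values, per the submitters' processing notes, and versions were not given in the sources used here. The method of normalisation was not given in the sources used here, nor whether the 4 states were normalised together. Sorted values of the 6 arrays of a state differed by a median of 0.04 to 0.08 log2, and those of all 24 arrays by 0.45, so changes between states also carry this difference of scale. No raw intensities were analysed here.

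Of the probe sets, 64 were controls, 20380 were assigned to 1 gene, 691 to several genes and 1555 to none. They covered 12393 genes, with 29 probe sets whose gene identifier was not found in the reference names. Each gene was represented by its probe set with the highest mean over the arrays, with probe sets of the x_at kind set aside where another existed. Genes above the 40th percentile of an array on at least 3 arrays were kept, which left 8600 genes.

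All 24 arrays were fitted in 1 linear model with a coefficient per group, with limma 3.58.1 in R 4.3.3, and 10 contrasts were taken. These were IFT88KD minus control in each of the 4 states, 3 changes between states in control cells, and 3 differences of the IFT88KD effect between states. P-values were adjusted by the Benjamini-Hochberg method over the 8600 genes of a contrast, and the threshold was an adjusted p of 0.05. Errors of log2 changes are standard errors (SE) from limma. A Python 3.11.15 program with matplotlib 3.10.9 and numpy 2.4.6 drew the plots.

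The gene lists and the rule for naming genes were fixed before the data were examined. There were 21 pathway lists and 6 lists of cell type markers. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists of its kind, and again with a correlation estimated from the data. The named genes were the 12 largest rises and falls of each IFT88KD contrast, the 10 of each control state change and the 5 of each difference of effects, among genes past the threshold whose arrays did not overlap in the simple contrasts. Up to 4 members of each list past the threshold were added. For 36 named results of the IFT88KD contrasts 56 other probe sets of the same gene were measured, of which 18 changed less by over 1.5 times, 1 of them with the opposite sign. For the control state changes these were 48 and 7 of 165, and for the differences of effects 1 and 1 of 3. Since the brightest probe set was used, the size of a change can depend on this choice.

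Replicate numbers were checked for pairing before fits with and without pairs were compared. Deviations of the IFT88KD and control arrays of equal number correlated across genes at 0.304 to 0.708 in proliferating, 0.252 to 0.487 in quiescent, 0.281 to 0.487 in replated and 0.450 to 0.671 in differentiating cells. Those of unequal number within a state correlated at 0.134 at most. Control arrays of equal number correlated at 0.156 to 0.421 between replated and quiescent cells and at 0.164 to 0.284 between differentiating and proliferating cells, but only at -0.0318 to 0.0672 between quiescent and proliferating cells. The design set before had no pairs, so the values given come from the unpaired model. A model with 12 blocks, 1 for each number within a state, is set beside it where it changes a call or a count.

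The alternatives were quantile normalisation, centring each array on its median, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, a variance trend with robust estimation, array weights, blocks, arrays of the compared groups only, each probe set on its own, fry, and leaving out each array in turn. The program was tested on simulated data for the quiescent IFT88KD contrast of 8600 genes, of which 200 were changed, simulated without pairs. It called 62.7% of 67 genes changed by 0.5 log2, 95.5% of 67 changed by 1 and 100% of 66 changed by 2, with 6 false calls among 178. With pairs simulated, the model without blocks called 53.7% of the genes changed by 0.5 log2 with 1 false call among 170. The model with blocks called 79.1% with 19 false calls among 205, so counts with blocks may hold more false calls than the threshold implies. Each figure rests on a single simulated data set, and without pairs simulated the model with blocks had 6 false calls among 166. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1, so none was used. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.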

Results

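Expression was compared between C2C12 myoblasts given siRNA against Ift88, which encodes an intraflagellar transport protein needed to build cilia, and cells given a negative control siRNA. The series asks how losing cilia bears on myoblast quiescence. Both siRNAs were followed in proliferating, quiescent, replated and differentiating cells, with 3 arrays in each of the 8 groups. Median signal was 3.60 log2 on proliferating, 3.81 on quiescent, 2.95 to 2.96 on replated and 3.69 to 3.71 on differentiating arrays, as group means. The number of arrays limits the precision.

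Ift88 mRNA fell in quiescent IFT88KD cells, by 0.69 log2 (SE 0.16, adjusted p = 0.0113), from 4.31 ± 0.12 to 3.63 ± 0.24 log2 (mean ± SD, n = 3). Its change was -0.52 (SE 0.16, adjusted p = 0.295) in proliferating and -0.59 (SE 0.16, adjusted p = 0.0535) in replated cells. All 3 IFT88KD arrays lay below all 3 control arrays in each of these 3 states. Within a single state chance alone gives such a separation, in either direction, for 10% of genes, and in all 3 states together for fewer. The change of Ift88 in differentiating cells was -0.01 (SE 0.16, adjusted p = 0.999), with means of 3.79 ± 0.25 and 3.80 ± 0.11 (SD, n = 3). A single probe set measured Ift88, with a signal near the median of most arrays. On the IFT88KD replated arrays it lay at percentiles 40.5 to 42.1, just above the filter percentile, so the size of the replated change is uncertain. With blocks for the replicate number within a state the adjusted p was 0.0429 in proliferating, 0.0019 in quiescent and 0.0080 in replated cells, and over the alternatives it ran from 0.0429 to 0.855, from 0.0019 to 0.0284 and from 0.0080 to 0.155. The quiescent call was lost without IFT88KD quiescent replicate 3 (-0.58, adjusted p = 0.073) and without control quiescent replicate 1 (-0.62, adjusted p = 0.0548), and the replated change passed without control replated replicate 2 (-0.74, adjusted p = 0.0216).

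**Figure D1:**
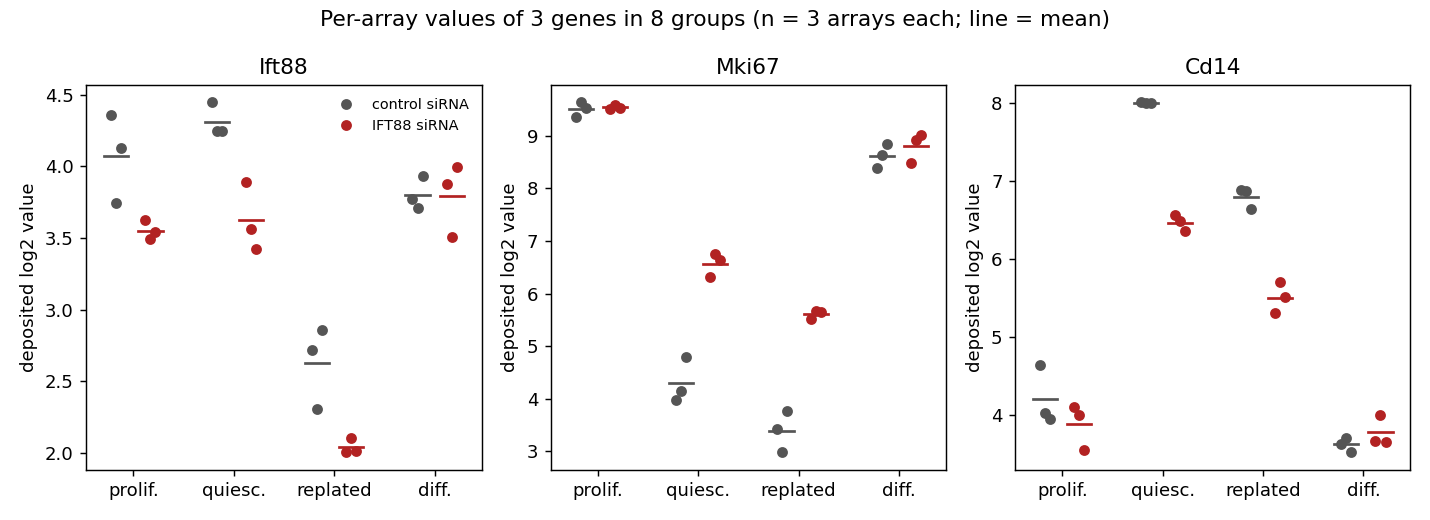
Log2 expression of Ift88, Mki67 and Cd14 on each array (points) with group means (lines) in the 8 groups. Mki67 was higher and Cd14 lower with IFT88 siRNA in quiescent and replated cells, by 2.27 and -1.54 and by 2.22 and -1.29 log2, and neither gene passed the threshold in the other states.

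The first comparison asks what IFT88 siRNA does in cycling cells. In proliferating cells it raised Ephx1, which encodes an epoxide hydrolase, by 1.21 log2 (SE 0.14, adjusted p = 3.09e-04, n = 3 per group). The p53 target genes Ccng1 and Zmat3 rose with it, by 0.88 (SE 0.13) and 0.93 (SE 0.16). So did Cd80, which encodes a ligand of costimulatory and inhibitory receptors on T cells, by 1.07 (SE 0.15). Fst, which encodes the activin and myostatin antagonist follistatin, rose by 1.17 (SE 0.19). Msln, which encodes the surface protein mesothelin, fell by 1.60 (SE 0.21, adjusted p = 3.79e-04), Itprid2 by 1.15 (SE 0.15), the secreted factor gene Mydgf by 0.90 (SE 0.11) and Aifm1, which encodes a mitochondrial flavoprotein, by 0.87 (SE 0.14). A second Cd80 probe set changed by 0.35 and 1 of 2 other Mydgf probe sets by -0.59. The changes passed for 31 genes, 16 higher and 15 lower.

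Among the lists in proliferating cells, p53 targets had a median change of 0.26 with 2 of 18 members higher and 0 lower (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.92e-05). All 20 sterol biosynthesis genes had a change under 0, with a median of -0.27, although 0 passed in limma and 7 were lower at an unadjusted p under 0.05 (5 lower adjusted over the list alone; camera adjusted p = 6.47e-11). With an estimated correlation the adjusted p was 0.0121 for p53 targets and 0.0112 for sterol genes, and 0.129 for both with blocks added. Muscle contraction genes had a median of 0.23 (camera adjusted p = 0.0017; adjusted p = 0.934 with an estimated correlation), and 0 of 47 passed in limma with 2 at an unadjusted p under 0.05. G2 and mitosis genes had a median of 9.3e-05, and 0 of 51 passed in limma with 1 at an unadjusted p under 0.05. The count of 31 genes was 166 (82 higher, 84 lower) with blocks and 232 with array weights. It was 20 without IFT88KD proliferating replicate 3 and 20 without control proliferating replicate 2. With arrays of the compared groups only, 0 genes passed in limma and 420 had an unadjusted p under 0.05.

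The comparison in suspended cells bears on quiescence itself. In quiescent cells IFT88 siRNA raised genes of the cell cycle, such as Mki67, a marker of cycling cells, by 2.27 log2 (SE 0.20, adjusted p = 2.05e-07, n = 3 per group). Ube2c, which encodes a ubiquitin carrier of the anaphase-promoting complex, rose by 2.03 (SE 0.19), Ccnb2, a mitotic cyclin gene, by 1.91 (SE 0.21), Birc5, which encodes survivin, by 1.87 (SE 0.15) and Top2a, a topoisomerase gene, by 1.77 (SE 0.16). The control cells held these genes far below proliferating cells, Ube2c by -5.41 (SE 0.19) and Birc5 by -5.74 (SE 0.15), so the rise made up part of the distance. Fgf7, which encodes a fibroblast growth factor, rose by 1.78 (SE 0.30), the chemokine gene Cxcl12 by 1.31 (SE 0.20), and Irs1, an adaptor of insulin signalling, by 1.13 (SE 0.17). A second Cxcl12 probe set changed by 0.86.

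Other genes fell in quiescent IFT88KD cells. Cd14, which encodes a lipopolysaccharide co-receptor, fell by 1.54 (SE 0.16, adjusted p = 1.93e-06), the lectin gene Clec10a by 1.74 (SE 0.14), the chemokine gene Ccl8 by 1.46 (SE 0.16), Cd68, a lysosomal membrane protein gene, by 1.32 (SE 0.15), the peptide hormone gene Cck by 1.75 (SE 0.19) and the protease inhibitor gene Slpi by 1.31 (SE 0.17). Clec10a and Cd68 lay under the filter percentile on all 3 IFT88KD quiescent arrays, so the sizes of their falls are uncertain. Control cells had raised Slpi by 7.23 (SE 0.17) on entering suspension. The threshold was passed by 447 genes, 248 higher and 199 lower, of which 74 and 18 changed by at least 1 log2. The count was 1173 (578 higher, 595 lower) with blocks and 275 without control quiescent replicate 2.

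G2 and mitosis genes were higher as a group in quiescent cells, with a median change of 1.19, and 45 of 51 members were higher, 0 lower and 6 not past the threshold (49 higher adjusted over the list alone; camera adjusted p = 2.21e-81; adjusted p = 0.0017 with an estimated correlation). DNA replication genes had a median of 0.29 with 9 of 41 higher (12 adjusted over the list alone), among them Uhrf1 at 1.33 (SE 0.15), Mcm5 at 1.26 (SE 0.18) and Mcm3 at 1.13 (SE 0.20), with Mcm5 under the filter percentile on all control quiescent arrays, and camera's adjusted p was 2.29e-09, but adjusted p = 0.536 with an estimated correlation. Other probe sets changed less, by 0.41 for Uhrf1 and by 0.09 for 1 of 3 others of Mcm3. Muscle contraction genes had a median of 0.51 with 3 of 47 higher and 0 lower (6 higher adjusted over the list alone; camera adjusted p = 1.24e-07; adjusted p = 0.536 with an estimated correlation), led by the myosin gene Myh1 at 1.98 (SE 0.44), which did not pass without control quiescent replicate 2 (1.72, adjusted p = 0.0587). Growth factor signalling had 4 of 37 higher and 1 lower with a median of 0.14 (camera adjusted p = 0.0079), extracellular matrix 7 of 41 higher and 3 lower with a median of 0.11 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0286) and ribosome biogenesis 1 of 25 higher with a median of 0.12 (camera adjusted p = 0.0286). None of these last 3 passed with an estimated correlation, where their adjusted p was 0.536, 0.536 and 0.596.

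The cilium list without Ift88 had a median of -0.07 in quiescent cells, with 0 of 30 higher and 2 lower in limma, Kif3a by -0.42 (SE 0.10) and B9d2 by -0.30 (SE 0.08). Kif3a, which encodes a motor subunit of intraflagellar transport, did not pass without IFT88KD quiescent replicate 3 (-0.38, adjusted p = 0.070) or without control quiescent replicate 3 (-0.37, adjusted p = 0.0774), and B9d2 passed only in 1 of the 6 such fits. Hedgehog pathway genes, whose signal passes through cilia, had medians of 0.05, 0.10, 0.03 and 0.12 in proliferating, quiescent, replated and differentiating cells, and 0 of 8 passed in limma in each state, with 2, 1, 0 and 2 at an unadjusted p under 0.05. Gli1 lay under the filter percentile in control proliferating and differentiating cells, and Hhip in control quiescent and differentiating cells. A lower Hedgehog signal could therefore have been missed. Other lists that camera did not call in quiescent cells had medians of 0.03 for arrest genes, 0.11 for immediate early genes, 0.08 for myogenic regulators, -0.08 for p53 targets, 0.03 for interferon response, 0.29 for inflammatory targets, -0.03 for sterol biosynthesis, -0.07 for glycolysis and hypoxia, -0.04 for the unfolded protein response, 0.14 for Wnt, 0.21 for Notch and 0.18 for TGF-beta genes. The actin cytoskeleton list had a median of -2.3e-03. With blocks camera called 3 of them higher, myogenic regulators (adjusted p = 0.0092), Notch (adjusted p = 0.0092) and inflammatory targets (adjusted p = 0.0125). None of the 3 passed with an estimated correlation added (adjusted p = 0.161, 0.424 and 0.436).

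**Figure D2:**
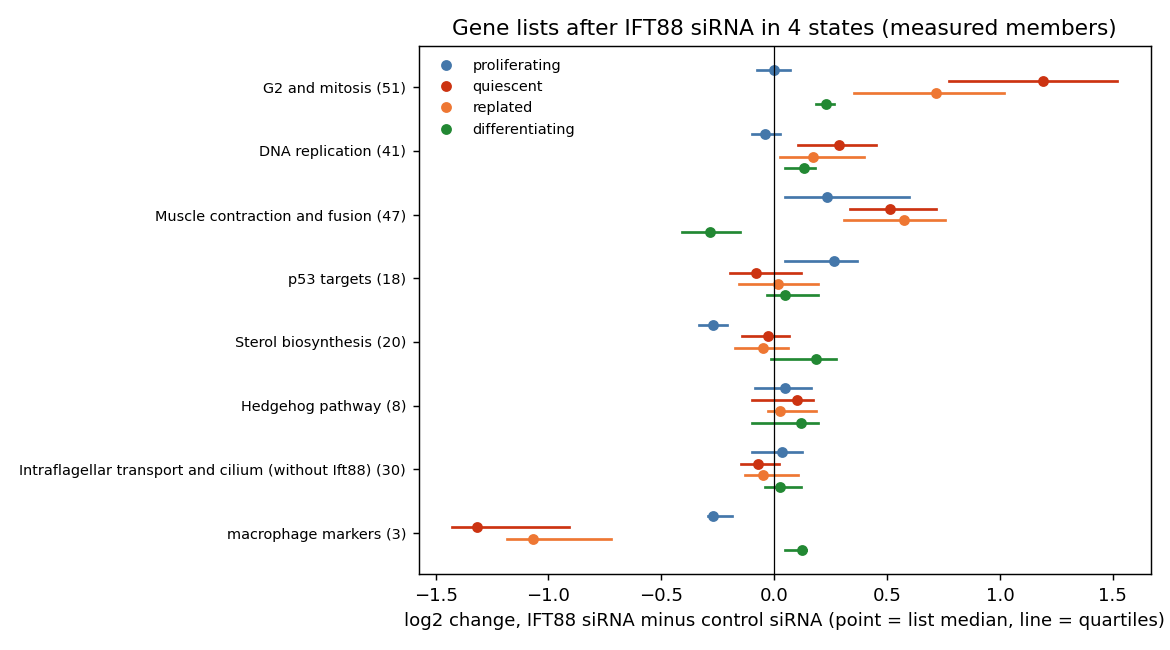
Median log2 change with IFT88 siRNA (points) and quartiles (bars) of the members of 8 gene lists in the 4 states. The G2 and mitosis list stood at 1.19 in quiescent and 0.72 in replated cells, against 9.3e-05 in proliferating and 0.23 in differentiating cells.

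Marker genes of macrophages were lower in IFT88KD quiescent and replated cells, although the cultures were myoblasts. Their median change was -1.32 in quiescent cells (2 of 3 lower, and 3 adjusted over the list alone; camera adjusted p = 6.71e-07) and -1.07 in replated cells (2 of 3 lower; camera adjusted p = 1.02e-06). Both held with an estimated correlation (adjusted p = 2.94e-04 and 3.44e-04), but each median is the change of Cd68, whose signal was low. Fibroblast markers had a median of 0.07 in quiescent cells with 1 of 4 lower, Pi16 by -0.46 (adjusted p = 0.0244), adipocyte markers -0.26 and bone and cartilage markers 0.12, where 0 of 4 and 0 of 2 passed in limma with 1 and 0 at an unadjusted p under 0.05. Of the endothelial and epithelial markers 0 were measured above the filter.

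Replated cells show how the siRNA bears on the return from suspension. At 2 h after replating, IFT88 siRNA raised Mki67 by 2.22 log2 (SE 0.20, adjusted p = 7.30e-07, n = 3 per group), Top2a by 2.01 (SE 0.16), Cdk1, which encodes the kinase that drives mitosis, by 1.71 (SE 0.13), and the complement gene C1ra by 1.65 (SE 0.23). The chemokine gene Cxcl12 rose by 1.46 (SE 0.20) and Nid2, a basement membrane gene, by 1.17 (SE 0.17). Mydgf fell by 1.22 (SE 0.11, adjusted p = 8.58e-07), Ccl8 by 1.36 (SE 0.16), Cd14 by 1.29 (SE 0.16), Slpi by 1.26 (SE 0.17) and Rgs5, a regulator of G protein signalling, by 1.19 (SE 0.18). In all 207 genes passed, 129 higher and 78 lower.

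G2 and mitosis genes in replated cells had a median of 0.72 with 29 of 51 higher and 0 lower (37 higher adjusted over the list alone; camera adjusted p = 1.16e-48). The call held with an estimated correlation (adjusted p = 0.0204) but not with blocks added (adjusted p = 0.0896). DNA replication genes had a median of 0.17 with 7 of 41 higher (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.50e-05), muscle contraction genes 0.57 with 1 of 47 higher (5 adjusted over the list alone; camera adjusted p = 6.74e-09), ribosome biogenesis genes 0.20 with 1 of 25 higher (camera adjusted p = 6.68e-04) and matrix genes 0.12 with 2 of 41 higher (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0073). Genes of the unfolded protein response had a median of -0.15 (camera adjusted p = 0.0065), and 0 of 27 passed in limma with 2 at an unadjusted p under 0.05. For these 5 lists the adjusted p was 0.601 with an estimated correlation. With blocks camera also called Notch genes higher (median 0.13, adjusted p = 0.0173; adjusted p = 0.389 with an estimated correlation added). The count of 207 genes was 955 (539 higher, 416 lower) with blocks, 80 with arrays of the compared groups only, 125 without IFT88KD replated replicate 1 and 111 without control replated replicate 2.

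The effects in quiescent and replated cells resembled each other. Across the 8600 genes the log2 changes correlated at r = 0.731 (Spearman rho = 0.60), where genes are not independent replicates. Higher in both states were 94 genes, such as Mki67, Top2a and Cxcl12, against 3.72 expected from the counts, and lower in both were 58, such as Cd14 and Ccl8, against 1.80. The expected counts treat the 2 states as independent, but replated cells had been in suspension until 2 h before. Control arrays of equal number also correlated between these states, at 0.156 to 0.421. The replated cells are therefore not an independent repeat of the quiescent result. Past the threshold in opposite directions there were 0, where limma gave 1405 and 1227 genes at an unadjusted p under 0.05. The other 5 pairs of states correlated at r = 0.176 to 0.312.

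**Figure D3:**
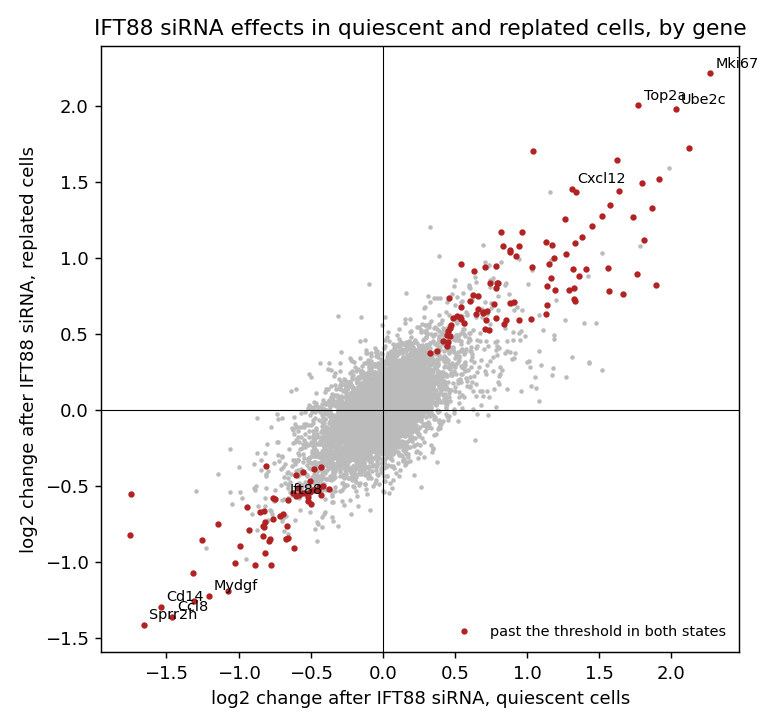
Log2 change with IFT88 siRNA in quiescent cells (x axis) and replated cells (y axis) of each of 8600 genes, with genes past the threshold in both states in red. The red genes lie in the upper right (94) and lower left (58).

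The last comparison of the siRNAs asks what IFT88 siRNA does as cells differentiate. In differentiating cells Klhl13, which encodes a ubiquitin ligase adaptor, rose by 1.01 log2 (SE 0.17, adjusted p = 0.0155, n = 3 per group), the exchanger gene Slc24a3 by 0.91 (SE 0.14), Psrc1, which encodes a spindle protein, by 0.87 (SE 0.14) and Ephx1 by 0.83 (SE 0.14). Bex1 fell by 1.54 (SE 0.23, adjusted p = 0.01) and Serping1, which encodes the inhibitor of complement C1 and lay under the filter percentile on all IFT88KD differentiating arrays, by 0.95 (SE 0.17). A second Psrc1 probe set changed by 0.39. Only 12 genes passed, 7 higher and 5 lower, and the others were Erap1, Pde8a and Stmn2 (higher) and Tas1r1, Fn3k and Stom (lower). G2 and mitosis genes had a median of 0.23 (camera adjusted p = 2.51e-14) and muscle contraction genes one of -0.28 (camera adjusted p = 4.41e-06), and in limma 0 of 51 and 0 of 47 passed with 3 and 4 at an unadjusted p under 0.05. Camera also called DNA replication (0.13), matrix (0.04) and sterol genes (0.18) higher and immediate early genes (-0.12) lower, and none of the 6 lists passed with an estimated correlation (adjusted p = 0.295 to 0.536). With blocks camera also called arrest genes higher (0.08, adjusted p = 0.0314) and TGF-beta genes lower (-0.14, adjusted p = 0.0314). Neither passed with an estimated correlation added (adjusted p = 0.340 for both). The 12 calls became 89 with blocks, 0 without IFT88KD differentiating replicate 3 (278 at an unadjusted p under 0.05 in limma), 1 without control differentiating replicate 1 and 2 without control differentiating replicate 3. With arrays of the compared groups only, 0 genes passed and 524 had an unadjusted p under 0.05.

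Differences of the IFT88 siRNA effect between states were tested directly. Mki67 responded more strongly in quiescent than in proliferating cells by 2.24 log2 (SE 0.28, adjusted p = 1.17e-04), Ccnb2 by 2.11 (SE 0.30) and Ube2c by 2.00 (SE 0.27), while Cck (-1.90, SE 0.26), Clec10a (-1.74, SE 0.19) and Ccl8 (-1.31, SE 0.22) responded more negatively. Msln, lower in proliferating cells, differed by 1.95 (SE 0.30), and Ephx1, higher there, by -1.36 (SE 0.20). These were among 107 genes, 77 with a positive and 30 with a negative difference, and the G2 and mitosis list had a median difference of 1.25 with 34 of 51 members positive (46 adjusted over the list alone; camera adjusted p = 6.2e-86; adjusted p = 0.0013 with an estimated correlation). DNA replication (0.38), growth factor (0.22), muscle (0.15) and sterol genes (0.18) were called positive and p53 targets (-0.22) negative by camera, and with an estimated correlation their adjusted p was 0.201 to 0.810. With blocks, a choice made after seeing the data, 330 genes differed, 197 positive and 133 negative.

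Replated and quiescent cells differed in their response at 5 genes. Clec10a (1.19, SE 0.19), of low signal in IFT88KD cells, had a less negative change in replated cells, and Fignl1 (-1.12, SE 0.18), Aoc3 (-0.94, SE 0.17), Rab30 (-0.83, SE 0.15) and Tmem100 (-0.83, SE 0.15) rose in quiescent cells by 1.43, 1.17, 0.64 and 0.96 and not past the threshold in replated cells. With blocks the adjusted p of Rab30 was 0.0527. DNA replication genes (median -0.07) and the unfolded protein response (-0.14) were called negative by camera, with an adjusted p of 0.985 with an estimated correlation. With blocks it also called inflammatory targets negative (-0.10, adjusted p = 0.0382; adjusted p = 0.790 with an estimated correlation added). The G2 and mitosis list had a median difference of -0.40 (camera adjusted p = 2.1e-23; adjusted p = 0.286 with an estimated correlation), and 0 of 51 passed in limma with 25 at an unadjusted p under 0.05 (1 higher and 14 lower adjusted over the list alone). Between differentiating and proliferating cells the response differed at 4 genes, Stmn2 (0.84, SE 0.16), Fst (-1.50, SE 0.27), Ak1 (-1.02, SE 0.17) and Ptp4a3 (-0.94, SE 0.17), each at an adjusted p of 0.0495. A second Ak1 probe set differed by 0.02. Sterol biosynthesis genes had a median difference of 0.49 there (camera adjusted p = 2.3e-16; adjusted p = 0.0015 with an estimated correlation and 0.0838 with blocks added), and 0 of 20 passed in limma with 13 at an unadjusted p under 0.05 (10 higher adjusted over the list alone). Camera called G2 and mitosis (0.24) and DNA replication genes (0.17) positive and muscle contraction genes (-0.62) and p53 targets (-0.25) negative in this second difference, none of them with an estimated correlation (adjusted p = 0.219 to 0.854). With blocks it also called immediate early genes negative (-0.09, adjusted p = 0.0305; adjusted p = 0.491 with an estimated correlation added). The 5 genes became 0 without IFT88KD quiescent replicate 3, control replated replicate 2 or control replated replicate 3 (256, 276 and 296 at an unadjusted p under 0.05), 2 without control quiescent replicate 1 or IFT88KD replated replicate 1 and 3 without IFT88KD replated replicate 3. The 4 genes became 0 to 2 without any 1 of the 12 arrays (219 to 392 at an unadjusted p under 0.05 where limma gave 0). With blocks, chosen after seeing the data, the 5 genes became 12 and the 4 genes 44. With arrays of the compared groups only both counts were 0, and limma gave 244 and 278 genes at an unadjusted p under 0.05.

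Control cells show what suspension itself changes. On entering quiescence, Rgs5 rose by 8.72 log2 (SE 0.18, n = 3 per group), the chemokine gene Cxcl1 by 8.31 (SE 0.26), Car9, a carbonic anhydrase gene induced by low oxygen, by 7.73 (SE 0.18), Dcn, which encodes the matrix proteoglycan decorin, by 7.65 (SE 0.32) and Apoe, an apolipoprotein gene, by 7.32 (SE 0.20). The mitotic motor gene Cenpe fell by 6.06 (SE 0.36), Cep55, needed for the end of cell division, by 5.97 (SE 0.16), and Mcm5, part of the replication helicase, by 5.62 (SE 0.18). The lower side lay under the filter percentile on all its arrays for Rgs5, Car9, Apoe, Cenpe, Cep55 and Mcm5, so these sizes are uncertain, and the other Rgs5 probe sets changed by 5.05 or more. Of 8600 genes 6132 passed, 3600 higher and 2532 lower, but 2734 higher and 3342 lower once arrays were centred, which moved the median change of all genes from 0.14 to -0.08. The G2 and mitosis list lay -4.83 and the DNA replication list -2.89 from the median of all genes, with all 51 and all 41 members lower.

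Other lists moved with them in suspension. Relative to the median of all genes, sterol biosynthesis lay at -2.22 with 18 of 20 lower, glycolysis and hypoxia at 2.13 with 22 of 22 higher, inflammatory targets at 2.07 with 16 of 18 higher, immediate early genes at 1.19 with 25 of 32 higher and arrest genes at 1.17 with 18 of 24 higher. Ribosome biogenesis lay at -1.51 with 24 of 25 lower and actin cytoskeleton genes at -1.02 with 16 of 18 lower. Among their members Idi1 of sterol synthesis fell by 4.89 (SE 0.11), Bnip3, induced by low oxygen, rose by 5.30 (SE 0.19) and the quiescence-linked gene Foxo3 rose by 2.61 (SE 0.13). Camera called 12 of the 21 lists, also growth factor, matrix and muscle genes, and 4 held with an estimated correlation: G2 and mitosis (adjusted p = 0.0324), DNA replication (0.0414), sterol biosynthesis (0.0136) and glycolysis (0.0369). The cilium list lay at 0.32 with 17 of 30 higher and 3 lower (camera adjusted p = 0.152), led by Bbs2 at 1.74 (SE 0.14) and Tctn2, under the filter percentile on all control proliferating arrays, at 1.66 (SE 0.14). Of the markers kept by the filter, those of adipocytes (2.71 as deposited, 4 of 4 higher) and macrophages (1.73 as deposited, 3 of 3 higher) were called by camera (adjusted p = 0.0285 for both). They were not called with an estimated correlation (adjusted p = 0.0705). The adipocyte markers Adipoq, Cidec and Lep and the macrophage markers Ptprc, Adgre1 and Lyz2 lay above the filter percentile on 0 control quiescent arrays, and Fabp4 on 1.

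Replating asks what changes within 2 h of renewed attachment. Relative to the median of all genes, which lay at -0.61 log2, Ccn2, a target of adhesion signalling, rose by 5.99 (5.37 as deposited, SE 0.34), the growth factor genes Pdgfb by 5.40 (SE 0.14) and Hbegf by 4.30 (SE 0.25), and Il6 by 4.95 (SE 0.56). A second Pdgfb probe set changed by 1.85 as deposited, against 4.79. Txnip, a glucose-responsive arrest gene, lay at -3.64 (SE 0.20), Fos at -3.45 (SE 0.65) and Adm, under the filter percentile on all control replated arrays, at -3.28 (SE 0.17), and the inhibitor gene Cdkn2d at -2.82 (SE 0.11). As deposited 827 genes were higher and 5749 lower, against 2343 and 3180 with quantile normalisation and 4022 and 1775 with centring, where the median lay at -0.10 and 0.25. RNA quality moved with the states, with a mean actin 3 prime to 5 prime difference of 0.73 on control proliferating, 1.26 on quiescent and 1.64 on replated arrays, 0.80, 0.47 and 1.21 for Gapdh, and 18S signal of 8.80, 7.64 and 7.06. Its share in the state changes was not separated. With members counted as deposited, ribosome biogenesis genes lay at 1.39 with 19 of 25 higher and 4 lower (camera adjusted p = 2.33e-15), inflammatory targets at 1.33 with 9 of 18 higher, the unfolded protein response at 0.75 with 11 of 27 higher, immediate early genes at 0.63 with 9 of 32 higher and 9 lower, and TGF-beta genes at 0.82 with 5 of 13 higher. None of the 8 lists called by camera passed with an estimated correlation (adjusted p = 0.0551 to 0.401), where ribosome biogenesis had an adjusted p of 0.118 and cilium genes 0.239. Cilium genes lay at -0.60 (camera adjusted p = 0.0011), with 28 of 30 lower as deposited, where 5749 of 8600 genes were lower, and 16 lower and 5 higher with centring, where 1775 were lower. Ttc8 and Ift81 changed by -2.46 and -2.33 as deposited. With centring camera did not call TGF-beta (adjusted p = 0.0501), immediate early (0.0605) or inflammatory genes (0.0605). The median of the G2 and mitosis list was -0.98 as deposited, -0.42 with quantile normalisation and -0.12 with centring.

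Differentiation was followed in control cells as well. After 48 h in low serum, Mybph, a myosin-binding protein gene, rose by 7.34 log2 (SE 0.59, n = 3 per group), the myosin genes Myl4 by 7.11 (SE 0.52) and Myh7 by 6.69 (SE 0.40), and Ckm, which encodes muscle creatine kinase, by 6.13 (SE 0.37). A second Myl4 probe set changed by 3.56. Myog, a regulator of differentiation, rose by 3.74 (SE 0.59) and the inhibitor genes Cdkn1c by 4.51 (SE 0.26) and Cdkn1a by 2.76 (SE 0.23). Id3 fell by 4.14 (SE 0.29) and Id2 by 3.25 (SE 0.18), both inhibitors of myogenic factors. Past the threshold were 4708 genes, 2102 higher and 2606 lower, against 1725 higher and 3223 lower once arrays were centred. Muscle contraction genes had a median of 5.08 with 45 of 47 higher and 1 lower, G2 and mitosis genes -1.37 with 51 of 51 lower, DNA replication genes -1.34 with 41 of 41 lower, matrix genes 0.59 with 24 of 41 higher and ribosome biogenesis genes -0.51 with 15 of 25 lower. Camera called these 5 lists (adjusted p = 7.6e-26 to 0.0011), and none passed with an estimated correlation (adjusted p = 0.174 to 0.527). Before differentiation the 3 control proliferating arrays already ranged in Myog from 4.94 to 8.74 log2.

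**Figure D4:**
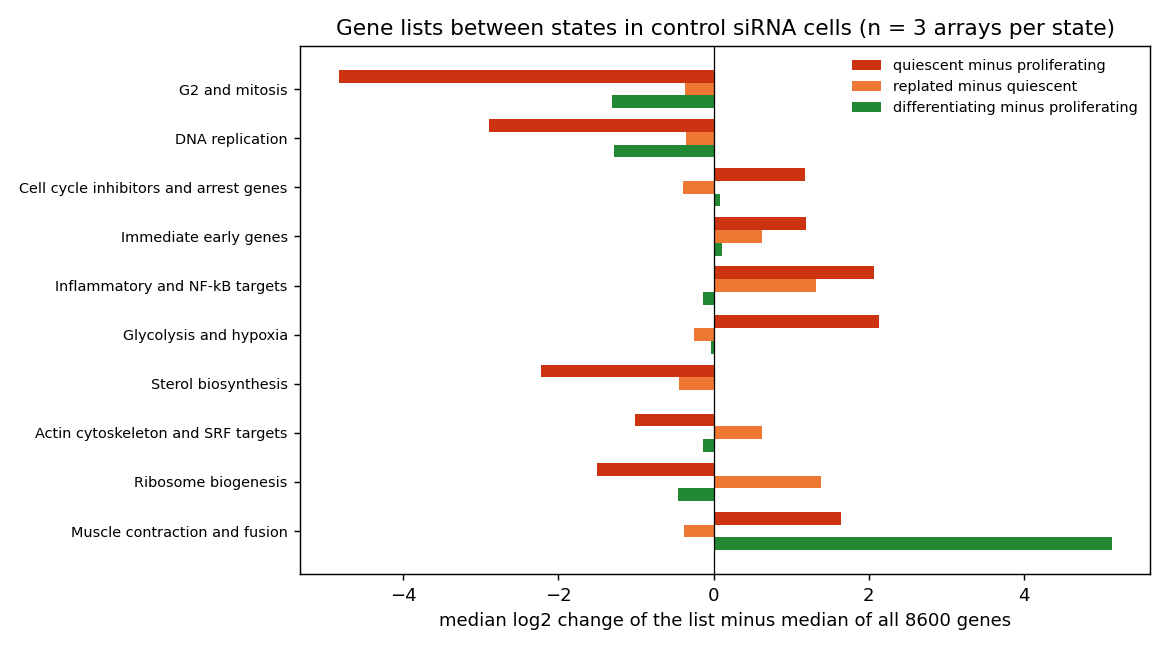
Median log2 change of 10 gene lists minus the median of all genes (bars) for the 3 state changes of control cells. G2 and mitosis genes lay at -4.83 in quiescent against proliferating cells, -0.37 in replated against quiescent and -1.31 in differentiating against proliferating cells.

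The changes on entering and leaving suspension were set against each other in control cells. They correlated at r = -0.192 across genes with a covariance of -0.185, against r = -0.502 and a covariance of -0.0123 in 100 simulations of unchanged groups that share the quiescent arrays. The simulated arrays were drawn independently, whereas control replated and quiescent arrays of equal number correlated at 0.156 to 0.421. Genes higher in quiescence and then lower numbered 2677 against 2406.6 expected from the counts, lower and then higher 361 against 243.5, higher in both steps 231 and lower in both 1518. With quantile normalisation these were 1490 against 1185.5, 970 against 778.4, 614 and 883. The covariance was then -0.189. The expected counts leave out the shared quiescent arrays, so part of the excess may come from them. Of the covariance they account for only -0.0123 in the simulations. In IFT88KD cells 5944, 6611 and 4358 genes passed on entering suspension, on replating and on differentiation. Of these 5446, 6171 and 3848 had also passed in the same direction in control cells, against 2175.0, 3922.0 and 1206.5 expected from the counts. Their G2 and mitosis list fell by 3.40 on entering suspension, where that of control cells fell by 4.69.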

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

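The tests of the scale between arrays, of the interferon response and of a mixture with proliferating cells were chosen only after the result was seen, as were the blocks in the differences of effects.

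The effect of IFT88 siRNA differed between states, which singled out the following results. Between quiescent and proliferating cells 107 genes differed, led by D17H6S56E-5 (2.29 log2), Mki67 (2.24), Ccnb2 (2.11), Ube2c (2.00) and Msln (1.95) with a positive difference and Cck (-1.90), Clec10a (-1.74), Cd93 (-1.38), Ephx1 (-1.36) and Ccl8 (-1.31) with a negative one, and the G2 and mitosis list had a median difference of 1.25. Between replated and quiescent cells 5 genes differed, Clec10a (1.19), Fignl1 (-1.12), Aoc3 (-0.94), Rab30 (-0.83) and Tmem100 (-0.83). Between differentiating and proliferating cells 4 genes differed, Stmn2 (0.84), Fst (-1.50), Ak1 (-1.02) and Ptp4a3 (-0.94), although a second Ak1 probe set differed by 0.02, and the sterol biosynthesis list had a median difference of 0.49. Among 1195 probe sets without a single gene name, which the comparisons of genes did not use, 49 passed the threshold for IFT88 siRNA in quiescent cells, against 1, 18 and 1 in proliferating, replated and differentiating cells. Of all 15066 probe sets tested, 622 passed in quiescent cells and 33, 275 and 8 in those other states. The probe sets without a single gene name thus passed about as often as all others in quiescent cells.

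Other splits of the same arrays were fitted in the same way. For each contrast of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real counts for IFT88 siRNA were 31, 447, 207 and 12 genes in proliferating, quiescent, replated and differentiating cells, and the highest counts of the other splits were 221, 1, 32 and 1, so that 2, 1, 1 and 1 of the 10 splits gave as many genes. For the state changes of control cells the real counts of 6132, 6576 and 4708 stood against 1, 0 and 0, and 1 of the 10 splits gave as many genes in each. The split of proliferating arrays with 221 genes points to a structure of the samples, in which arrays of equal number resemble each other. Among the 4 splits that part all pairs, fewer still, the highest other count in limma was 0 in each of the 4 states. Every other split mixes the 2 compared groups, so their real difference adds to its spread and tends to lower its count. Low counts of other splits therefore do not exclude chance, for the siRNA contrasts or the state changes.

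For the differences of effects, 100 relabellings of siRNA within the states were drawn. As many genes as the real 107, 5 and 4 were given by 6, 11 and 10 of them, the real labels included, so chance was not excluded by these shares, and the highest other counts were 437, 951 and 96. The 951 genes came from the relabelling that turned the labels of quiescent cells and kept those of replated cells, which adds the real effects instead of subtracting them, and without it 10 gave 5 or more (highest other 291). The 5 relabellings with more than 107 genes all kept the real labels of quiescent cells and did not part all pairs, so they hold the quiescent effect itself. Among relabellings that part all pairs, 1 of 16 gave 107 or more (highest other 4), 5 of 14 gave 5 or more (highest other 951, and 170 once that relabelling is left out) and 1 of 16 gave 4 or more (highest other 1).

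The first pattern weighed was the rise of G2 and mitosis genes in quiescent IFT88KD cells, by a median of 1.19. A difference of scale between the deposited values was argued against, since sorted values of the 6 quiescent arrays differed by a median of only 0.06 log2. That likeness may come from the normalisation, whose method was not given, so it does not bear on the scale before it. Quantile normalisation could therefore change little, and the median stayed at 1.19. RNA degradation was argued against as well, since the mean actin 3 prime to 5 prime difference was 1.17 on IFT88KD and 1.26 on control quiescent arrays (0.55 and 0.47 for Gapdh). The actin difference as a covariate could thus also change little, and the median was 1.20 with it. A share of cells that had kept or regained the whole proliferating profile cannot be told apart from a rise limited to cell cycle genes. The 62 matched genes rose by a median of 0.55 (bootstrap SE 0.06), too near the bound of 0.5 of the list's own median. Their median excess in proliferating cells was 3.92 log2, against 4.69 for the list. Only members of the G2 and mitosis and DNA replication lists were kept out, so they may hold other cell cycle genes. Bootstrap SEs resample genes, not arrays. A mixture holding 5.54% proliferating cells would have changed sterol genes by 0.17, muscle genes by -0.05 and DNA replication genes by 0.36, where -0.03 (bootstrap SE 0.04), 0.51 (bootstrap SE 0.04) and 0.29 (bootstrap SE 0.06) were seen, but the profile of such cells in suspension is assumed. The share also takes signal as linear down to background. The median level of the G2 and mitosis list in control quiescent cells was 2.80 log2, near the mean 40th percentile of 2.55 on those arrays. The rise may therefore be a weaker arrest in all cells or cycling in a few, and that a lower Ift88 level brings either about is a hypothesis that was not tested.

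The second pattern was a set of 100 genes with an unadjusted p under 0.05 and 1 direction in proliferating, quiescent and replated IFT88KD cells, against 3.07 expected if the states were independent. Quiescent and replated effects correlated at r = 0.73, so they were not independent and the expected count is too low. An interferon response to the siRNA was argued against, since the highest median of that list in the 4 states was 0.12 and camera called it in none. An siRNA effect that does not need a lower Ift88 level stays open, although its test met the bound set beforehand against it, with a median change of 0.13 (bootstrap SE 0.02) in differentiating cells, under 0.5 of the median of 0.47 in the other 3 states. That bound was set aside only after the value was seen. Ift88 itself was at the control level in differentiating cells (-0.01, SE 0.16), so a siRNA that had faded would shrink effects of both kinds. The test therefore cannot decide the question. In differentiating cells 79 of the 100 genes kept their direction, 27 of them with an unadjusted p under 0.05 in limma. Whether the 100 genes follow from Ift88 or from other targets of the siRNA cannot be told apart, although either could be the source. No second siRNA or restored Ift88 was measured.

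The third pattern was the fall of macrophage marker genes in quiescent and replated IFT88KD cells. If macrophages were present, their other abundant genes should be seen, but 3 of the 4 markers Ptprc, Adgre1, Csf1r and Lyz2 lay under the filter percentile on all control quiescent arrays, at 1.12, 1.67 and 1.45 log2 for Ptprc, Adgre1 and Lyz2. Csf1r lay at 3.54 and Cd14 at 8.01, but Cd68, at 3.27 and under the filter percentile on all IFT88KD quiescent arrays, did not reach the 80th percentile that the test required. The test therefore did not reach its bound against fewer macrophages in the IFT88 siRNA cultures. The cells were a myoblast line, however, and Ptprc, Adgre1 and Lyz2 lay above the filter percentile on 0 arrays of every group. These values argue against macrophages as the source, with Csf1r, above it on all 3 control quiescent arrays, going the other way. Lower expression of Cd14 and Cd68 by myoblasts may be part of a less complete response to suspension, an explanation that was not tested. Lists higher in suspended control cells did not fall likewise in quiescent IFT88KD cells. Inflammatory targets changed by 0.29, immediate early genes by 0.11, arrest genes by 0.03 and glycolysis and hypoxia by -0.07. Slpi (-1.31) and Rgs5 (-1.07), also raised in suspension, did fall. A weaker response in general is thus not shown.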

How the results depend on the processing

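The fits with an actin covariate, those without both arrays numbered 3 and the blocks in the differences of effects were chosen only after the result was seen.

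Over the alternatives 274 values of the main results were the same in direction and side of the threshold or within 1.5 times of the count, 61 counts moved, 7 values came past the threshold and 4 no longer passed. The cause was not tested for the changes below unless fewer arrays or genes were used. With quantile normalisation Ift88 in replated cells was -0.75 (adjusted p = 0.0194), the difference of replated and quiescent effects had 0 genes (264 at an unadjusted p under 0.05 in limma), and Cdon on replating was 0.01, reversed from -0.81. With centring Cdon was 0.0508 and Sufu 0.11, reversed from -0.75. Without a filter the difference of differentiating and proliferating effects had 0 genes (451 at an unadjusted p under 0.05). With the filter at the 60th percentile Ift88 in replated cells was -0.59 (adjusted p = 0.0435), differentiating cells had 5 genes, and the difference of replated and quiescent effects had 1. With the mean of a gene's probe sets the difference of differentiating and proliferating effects had 0 (296), and with a variance trend and robust estimation that of replated and quiescent effects had 2.

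Array weights gave 232, 811, 762 and 28 genes for IFT88 siRNA in proliferating, quiescent, replated and differentiating cells, and 285, 13 and 18 for the 3 differences. Blocks for the number across states gave 394 in replated cells, with Ift88 at -0.59 (adjusted p = 0.0144). Blocks within a state gave 166, 1173, 955 and 89 genes, differences at 330, 12 and 44 genes, and Ift88 at -0.52 (adjusted p = 0.0429) in proliferating and -0.59 (adjusted p = 0.0080) in replated cells. Arrays of the compared groups only gave 0 genes in proliferating (420 at an unadjusted p under 0.05), 80 in replated and 0 in differentiating cells (524), and 0 for the last 2 differences (244 and 278). Each probe set on its own gave 10351, 11011 and 7954 for the control state changes, where more features were tested, and 2 and 0 (491) for the last 2 differences. The G2 and mitosis list in differentiating cells, 0.23, did not pass with an estimated correlation (adjusted p = 0.487) or with fry (adjusted p = 0.441). With the actin covariate Ift88 in replated cells was -0.59 (adjusted p = 0.0471). Without both replated arrays numbered 3 replated cells had 110 genes and their difference from quiescent cells 0 (276), and without both proliferating ones the counts were 16 and, against differentiating cells, 1.

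Leaving out 1 array gave 20 to 35 genes in proliferating, 275 to 344 in quiescent, 111 to 272 in replated and 0 to 12 in differentiating cells, 5794 to 5975, 6307 to 6446 and 4101 to 4564 for the state changes, and 77 to 102, 0 to 7 and 0 to 2 for the differences. Ift88 ran from -0.69 to -0.38, -0.82 to -0.58, -0.74 to -0.47 and -0.11 to 0.13, and the G2 and mitosis list from -0.04 to 0.04, 1.07 to 1.32, 0.65 to 0.76 and 0.16 to 0.35. Of 2706 values of named genes without 1 array, 265 no longer passed, and of the named genes with arrays of the compared groups only 71. A floor of 16 was not run, since the values were already log2, nor another Ift88 probe set, since there was none. Genes of low signal, such as Cd68, which lay under the filter percentile on all proliferating and all IFT88KD quiescent arrays, were limited by the background of the arrays.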

Other observations

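The counts across all 4 states were chosen only after the result was seen.

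With IFT88 siRNA 12 genes were higher and 15 lower in all 4 states at an unadjusted p under 0.05, against 0.038 and 0.034 expected if the states were independent. The effects in quiescent and replated cells correlated at r = 0.73, so the states were not independent. These expected counts are therefore too low, and the excess does not measure a shared effect. Mydgf changed by -0.90, -1.21, -1.22 and -0.42 log2 in proliferating, quiescent, replated and differentiating cells (SE 0.11 each), Itprid2 by -1.15, -0.77, -1.02 and -0.44 (SE 0.15 each) and the lysosomal enzyme gene Galc by -0.74, -0.66, -0.76 and -0.37 (SE 0.13 each). Zmat3 changed by 0.93, 0.61, 0.72 and 0.35 (SE 0.16 each) and Cxcl12 by 0.65, 1.31, 1.46 and 0.61 (SE 0.20 each). None of these 5 genes passed the threshold in differentiating cells, and Cxcl12 did not pass in proliferating cells.

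Stmn2, which encodes a regulator of microtubules, was lower in quiescent (-0.76, SE 0.11) and replated (-0.72, SE 0.11) IFT88KD cells and higher in differentiating ones (0.55, SE 0.11). The call in differentiating cells was lost without any 1 of their 6 arrays (adjusted p = 0.0555 to 0.300).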
